A study of Mus musculus with 6 samples.

How the data were processed

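Messenger RNA was measured by sequencing in 6 mouse libraries, 3 labelled control shRNA and 3 labelled VprBP shRNA. The labels give the cells as bone marrow-derived macrophages of wild-type genotype. An shRNA is a short hairpin RNA that lowers the transcript it matches. VprBP is the older name of Dcaf1, a substrate receptor of the CRL4 ubiquitin ligase for which a histone kinase activity has also been reported. RNA was purified on RNeasy columns and made into libraries with a SMARTer mRNA kit, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

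The values are expected counts per gene as deposited by the authors, not scaled between libraries. Per the submitters' processing notes, Partek software and the mouse build mm10 (GRCm38) were used. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. Between 62.1% and 64.5% of the values in a library were whole numbers within 0.001, and the rest had fractions, as arise when reads that fit several genes are shared among them. Such sharing makes genes with near-identical copies uncertain, and with no stated strand setting the reads of overlapping or antisense genes cannot be told apart. The table listed 18908 gene IDs, 14222 of them protein coding, with 15 repeated symbols. The lowest total of a listed gene over the 6 libraries was 10 counts, so a gene with fewer counts than that has no row. Of the 18908 IDs, 18501 (97.8%) matched GENCODE M21 on GRCm38 with their version, and all 18501 of these had the same coordinates. Every per-sample column was assigned to a library by its name.

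The deposited estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood F test with TMM scaling and group as the only term. Genes passing filterByExpr were tested, 14641 in all. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are CPM, counts scaled to a common library size with TMM factors, given as mean ± SD over the 3 libraries of a group. Differences are VprBP-labelled minus control-labelled on the log2 scale. The Dcaf1 level was also compared by a two-sided exact permutation test of 3 against 3 log2 values.

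Total counts were 21838875, 16839445 and 17386596 in control-labelled libraries 1, 2 and 3, and 17846944, 17825340 and 18407356 in VprBP-labelled libraries 1, 2 and 3. A count of 0 in a library of this depth allows a level of up to 0.144 to 0.186 CPM, taken as 3 counts. Such floors and the counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group had no counts for a gene, its fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts it is given as a ratio of scaled counts with its 95% counting interval. All other folds come from the edgeR log2 difference. They need not equal the ratio of the printed means and are not to be ranked against the ratios of counts.

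Before the data were examined, 28 gene lists, the test, the alternatives and the rule for named genes were fixed. The lists covered osteoclast differentiation and resorption genes, negative regulators of osteoclast differentiation, CRL4-DCAF1 ligase subunits and partners, macrophage identity genes, interferon-stimulated genes, inflammatory and NF-kB target genes, p53 targets, mitotic and DNA replication genes. They also covered lysosome and V-ATPase, oxidative phosphorylation, glycolysis, cholesterol synthesis, unfolded protein and integrated stress response, immediate-early and heat shock, MHC class II, ribosomal protein and nucleolar genes. The remaining lists were markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells, stromal cells, erythroid cells, megakaryocytes, endothelial cells and osteoblasts. Lists with at least 5 tested members were tested against all other genes with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, which asks whether a list's own genes move on balance in a single direction, were alternatives. Named genes were Dcaf1, then the 10 genes higher and the 10 lower with the largest change among called genes with a mean of at least 10 CPM and no overlap between groups. Predicted genes, Rik clones and pseudogenes were left out of these. The 5 genes higher and the 5 lower with the smallest p were added, with up to 5 members per list by smallest p and any member needed to give a direction. Genes of the pigment cell, pan-leukocyte, proteasome, collagen, NRF2 target, MHC class I, myelin and melanosome groups were chosen after the data were seen.

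Alternatives were DESeq2 size factors in edgeR, library size only, upper quartile scaling, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, a minimum absolute log2 difference of 1, and a prior count of 0.5. A fit without the 50 most abundant genes was added after the data were seen. The procedure was tested on simulated counts for the same 14641 genes, with 200 planted changes. It recovered 64% of 50 genes changed 1.5-fold, 86% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold. It called 17 of 14441 unchanged genes (0.118%). The planted changes were balanced up and down and far fewer than the 10974 genes called in the data. These rates therefore do not tell how the scaling behaves when most genes change. The counts of libraries within a group were compared to look for duplicate libraries, and no pair agreed within sampling noise (chi-square per degree of freedom between 3.18 and 5.94). That spread may be technical and does not show that the libraries are biological replicates. Each was counted as its own sample, as labelled. No library was left out. Some genes that the rule picked or that belong to the lists are counted but not reported here by name.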

Results

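The study's title and design text concern VprBP in osteoclast differentiation, and the design implies a single comparison, of cells given an shRNA against VprBP with cells given a control shRNA. Counts were analysed for 6 libraries, 3 per label. Total counts ranged from 16839445 to 21838875, and 17687 to 17953 genes had at least 1 count in a library. The targeted transcript differed little between the labels, and transcripts of another cell type than the labelled one were among the most abundant. The groups are therefore called control-labelled and VprBP-labelled libraries throughout, every direction below is a direction between labels, and none is ascribed to loss of VprBP.

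The targeted gene came first as a check of the labels. Dcaf1 (VprBP; ENSMUSG00000040325.16; GRCm38 chromosome 9, 106821874 to 106880992, plus strand) was measured at 42.2, 43.5 and 40.7 CPM in the control-labelled libraries and at 36.0, 34.6 and 36.8 CPM in the VprBP-labelled libraries. The means were 42.1 ± 1.42 and 35.8 ± 1.11 CPM (SD, n = 3 each). The VprBP-labelled mean was 84.9% of the control-labelled mean, with a 95% interval of 76.5% to 94.2%. The log2 difference was -0.24 (SE 0.07, edgeR adjusted p = 0.00625), and it was lower in 3 of 3 libraries. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Of the 14641 tested genes, 81.0% changed by more than Dcaf1. With scaling by library size only, the difference was -0.12 and was no longer called (adjusted p = 0.137).

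Transcripts of pigment cells were among the most abundant in all 6 libraries, and most transcripts that mark macrophages were scarce. Tyrp1, an enzyme of melanin synthesis, stood at 6778 ± 262 CPM in the control-labelled and 7166 ± 181 CPM in the VprBP-labelled libraries, and Dct, another such enzyme, at 5807 ± 86.5 and 8737 ± 243 CPM. Pmel, which forms the fibrils of the melanosome, stood at 6971 ± 145 and 2505 ± 68.5 CPM. The summed level of 8 pigment cell genes was 21290 ± 201 CPM in the control-labelled and 19843 ± 254 CPM in the VprBP-labelled libraries. They were chosen on abundance after the data were seen, so the height of their sum is no test. Of the 22 macrophage identity genes, Csf1r, Adgre1, Itgam, Spi1, Tyrobp and Aif1 are among those without a row in the table used here. The lowest total of a listed gene was 10 counts over the 6 libraries. Only 7 of the 22 genes have a row. Gpnmb (11213 ± 71.3 and 6321 ± 158 CPM) and Apoe (1702 ± 176 and 1486 ± 133 CPM), which pigment cells also express, held nearly all of their counts. The other 5 summed to 39.1 ± 1.77 and 17.8 ± 0.915 CPM, at most 0.192% of the pigment gene sum in any library. Most of the control-labelled sum was Cd68, at 31.6 ± 1.20 CPM against 1.01 ± 0.270 CPM in the VprBP-labelled libraries, and Mertk, a receptor for the uptake of dead cells, stood at 5.35 ± 0.739 and 13.3 ± 0.696 CPM. Lyz2, the lysozyme gene of macrophages, stood at 1.05 ± 0.212 and 2.51 ± 0.304 CPM, and Cd14, a lipopolysaccharide co-receptor, at 1.03 ± 0.241 and 0.785 ± 0.314 CPM. Among the 6 tested macrophage genes, 2 were higher (Mertk and Lyz2), 3 lower and 1 not called in the VprBP-labelled libraries, and 2 higher and 3 lower when adjusted over the list alone. The list as a whole was not called (median log2 difference -0.29, camera adjusted p = 0.586).

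**Figure D1:**
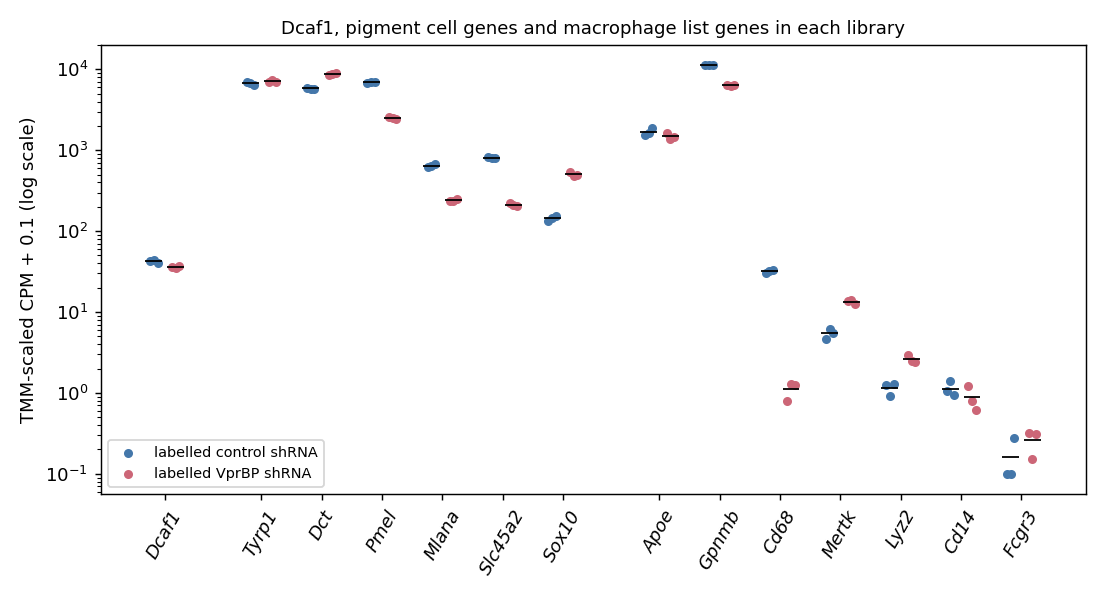
Level of Dcaf1, 6 pigment cell genes and 7 macrophage list genes in each library, in TMM-scaled CPM plus 0.1 on a log axis; points are libraries, coloured by label, and bars are means of 3. Tyrp1, Dct and Pmel lie at or above 2441 CPM in all 6 libraries, whereas Lyz2 and Cd14 lie below 3 CPM, and Dcaf1 lies between 34.6 and 43.5 CPM.

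The labelled groups nevertheless differed across most of the transcriptome. Of 14641 tested genes, 10974 (75.0%) were called, 5552 higher and 5422 lower in the VprBP-labelled libraries. Of these, 2843 were higher and 2080 lower by at least 1 on the log2 scale, and 1279 and 535 by at least 2. The groups did not overlap for 11299 genes (77.2%), where chance gives 10%. Library pairs within a group correlated at 0.993 to 0.994 across genes and pairs between groups at 0.885 to 0.888, genes not being independent replicates. The leading principal component held 87.9% of the variance and separated the labels. The biological coefficient of variation within groups was 6.70%. Scaling by library size only moved the median of all genes by 0.12 on the log2 scale and gave 6160 higher and 4719 lower calls.

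Among the genes most raised in the VprBP-labelled libraries, Lgi4, a secreted protein needed for peripheral myelination (chromosome 7, 31059342 to 31070935), had no counts in the control-labelled libraries and 24.3 ± 1.78 CPM in the others, at least 435-fold higher. Gas7 was 563-fold higher (0.208 ± 0.162 against 129 ± 2.54 CPM), Lgr6, a receptor for R-spondins, 514-fold, and Kcna5, a voltage-gated potassium channel, 422-fold. Saa3, an acute phase serum amyloid gene, was higher by a ratio of 362 (counting interval 124 to 1760), and Clca3a1, which has near-identical relatives and is uncertain, by a ratio of 478 (163 to 2322). Serpina3n rose 279-fold, the adhesion protein Cntn1 243-fold, the matrix proteoglycan Prelp 234-fold and the sodium pump subunit Atp1b2 163-fold. Gas7, Lgr6, Kcna5, Serpina3n and Cntn1 had 12, 11, 6, 6 and 7 counts over the control-labelled libraries, so the size of their folds is uncertain. The smallest p-values on this side belonged to Prelp and 4 more genes. Cp, the copper-carrying ferroxidase ceruloplasmin (chromosome 3, 19957054 to 20009145), rose 97.3-fold from 38.7 ± 3.45 to 3775 ± 265 CPM. Mbp, a structural protein of myelin, rose 33.6-fold, the secreted carbonic anhydrase Car6 39.4-fold and the glycolytic enzyme Eno1, uncertain because of near-identical copies, 11.4-fold.

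Among the genes most lowered in the VprBP-labelled libraries, Hspa5, the main chaperone of the endoplasmic reticulum (chromosome 2, 34771970 to 34777547), was 13.2-fold lower (18399 ± 345 against 1389 ± 54.5 CPM). Hmox1, the inducible haem oxygenase (chromosome 8, 75093621 to 75100589), was 22.4-fold lower (9747 ± 71.2 against 435 ± 8.39 CPM). The stress-induced transcription factor Atf3 was 59.5-fold lower, the phosphatase subunit Ppp1r15a, which reverses the translational block of the stress response, 15.8-fold, and Dnajb9, a co-chaperone of the endoplasmic reticulum, 12.3-fold. Heat shock genes among them were Hspa1b, 28.7-fold lower but uncertain because of its near-identical copy Hspa1a, Hspb1, 15.2-fold lower, and Zfand2a, 16.1-fold lower. Slc18a1, a vesicular monoamine transporter, was 198-fold lower, the lysosomal glycoprotein Cd68 31.0-fold, the interleukin subunit Il23a 18.5-fold and the natriuretic peptide Nppb 15.8-fold. Each of the 27 genes picked by size of change or p, and Dcaf1, had an edgeR adjusted p below 0.05 and the same direction in 3 of 3 libraries. For the 27 the rule itself required the adjusted p, and for those picked by size also the lack of overlap between groups.

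Genes of osteoclast differentiation and resorption, the subject of the study, moved in both directions. Of 30, 24 have a row and 20 were tested. Of these 20, 13 were higher, 6 lower and 1 not called in the VprBP-labelled libraries (13 and 6 adjusted over the list alone). Tnfrsf11a, Calcr, Dcstamp, Ocstamp, Atp6v0d2 and Siglec15 have no row, and Acp5, Ctsk, Oscar and Prdm1 had too few counts to be tested. Acp5 stood at 0.122 ± 0.105 and 0.246 ± 0.245 CPM and Ctsk at 0.917 ± 0.443 and 0.122 ± 0.167 CPM in the control-labelled and VprBP-labelled libraries. The calls in this list say nothing about these genes. Mitf, a transcription factor of osteoclasts and also of pigment cells, was 3.44-fold higher (27.5 ± 1.02 against 94.6 ± 4.04 CPM), the surface protein Cd109 2.43-fold and the tyrosine kinase Src 2.21-fold. Mmp9, a matrix-degrading protease, rose 15.3-fold from 0.566 ± 0.104 to 8.66 ± 0.669 CPM. Clcn7, the lysosomal chloride exchanger, fell 3.84-fold from 399 ± 11.8 to 104 ± 3.76 CPM. More members rose than fell, but the summed level was 1878 ± 27.8 CPM in the control-labelled and 1732 ± 20.05 CPM in the VprBP-labelled libraries. The list was not called by camera (median log2 difference 0.78, adjusted p = 0.13, and 0.209 as the adjusted p with an estimated correlation). Of 27 negative regulators of osteoclast differentiation, 21 were tested, with 13 higher, 6 lower and 2 not called (13 and 6 adjusted over the list alone). The NF-kB inhibitor Nfkbia was 3.01-fold higher, the phosphatase Ptpn6 13.9-fold and the cytokine signalling inhibitor Socs3 3.28-fold, whereas Nfkb2 was 1.99-fold lower. This list was not called either (median 0.60, adjusted p = 0.199, and 0.395 with an estimated correlation).

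Of the 10 ligase subunits and partners of DCAF1, 3 were higher, 3 lower and 4 not called in the VprBP-labelled libraries, with the same 3 and 3 when adjusted over the list alone. Cops5, a subunit of the COP9 signalosome, was 1.86-fold lower and Nedd8, the modifier that activates cullins, 1.38-fold lower, whereas Ddb1, the adaptor that joins DCAF1 to the cullin, was 1.14-fold higher. The scaffold Cul4a was not called (105 ± 7.48 and 97.8 ± 5.32 CPM). The list was not called (median 0.000328, mean -0.06, adjusted p = 0.911). The median lay just above 0 while the mean and camera pointed down, and upper quartile scaling turned the sign of the median.

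Genes of cell division were higher in the VprBP-labelled libraries. All 20 mitotic genes rose (20 adjusted over the list alone), with a median log2 difference of 3.99. Mki67, the proliferation marker, rose 23.4-fold from 15.2 ± 1.75 to 356 ± 23.6 CPM, Top2a, which untangles chromosomes, 17.9-fold, and the mitotic kinase Aurkb 34.6-fold. Of 21 DNA replication genes, 20 rose and 1, the repair glycosylase Ung, fell (20 and 1 adjusted over the list alone), with a median of 1.93. The helicase subunit Mcm5 rose 14.9-fold and Rrm2, which makes deoxyribonucleotides, 5.67-fold. Camera called both lists (adjusted p = 4.77e-09 and 1.34e-06), but with an estimated correlation the adjusted p was 0.0571 for each.

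All 16 glycolysis genes were higher in the VprBP-labelled libraries (16 adjusted over the list alone, median 1.51), and their summed level was 5194 ± 84.0 CPM in the control-labelled and 20408 ± 605 CPM in the VprBP-labelled libraries. The phosphofructokinase Pfkl rose 14.7-fold, lactate dehydrogenase Ldha 4.86-fold and Pgk1 3.96-fold. Camera called the list (adjusted p = 3.85e-07), with an adjusted p of 0.0752 when the correlation was estimated. Nuclear genes of oxidative phosphorylation were mixed, with 10 higher, 6 lower and 4 not called of 20 (10 and 6 adjusted over the list alone). Sdha was 1.95-fold higher and Cox5b 1.75-fold lower, and the list was not called (median 0.12, adjusted p = 0.45). Genes on the mitochondrial genome took 9.48%, 9.26% and 8.65% of the counts in the control-labelled libraries and 4.89%, 5.56% and 5.17% in the VprBP-labelled ones. This share moved with the labels, and so alongside each list called here. It is uncertain in size, because nuclear copies of mitochondrial genes took a further 2.28% to 2.48% and 0.963% to 1.11% of the counts.

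Stress response genes were lower in the VprBP-labelled libraries. Of 20 unfolded protein and integrated stress response genes, 15 fell and 5 rose (15 and 5 adjusted over the list alone, median -1.82), and the summed level was 29305 ± 278 CPM in the control-labelled and 4853 ± 61.3 CPM in the VprBP-labelled libraries. Besides Hspa5 and Dnajb9, Creld2 fell 11.5-fold, the transcription factor Ddit3 7.65-fold and the chaperone Hyou1 5.26-fold. The 5 that rose were Phgdh, Psat1 and Aldh18a1, which make amino acids, with Ddit4, an inhibitor of growth signalling, and the lipoprotein receptor Vldlr. Of 16 tested immediate-early and heat shock genes, 12 fell, 2 rose (Nr4a1 and Klf2) and 2 were not called (12 and 2 adjusted over the list alone, median -1.26). The heat shock gene Hsph1 fell 7.57-fold, the co-chaperone Dnajb1 6.64-fold and the transcription factor Jun 3.36-fold. Of 19 p53 target genes, 16 fell, 1 rose (Sesn1) and 2 were not called (16 and 1 adjusted over the list alone, median -0.70). The growth inhibitor Btg2 fell 6.92-fold and the stress hormone Gdf15 3.60-fold. Camera called the 3 lists (adjusted p = 0.0006, 0.00191 and 0.000463), and with an estimated correlation the adjusted p values were 0.0752, 0.0692 and 0.0692.

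Cholesterol synthesis, lysosome and nucleolar genes were also lower in the VprBP-labelled libraries. Of 18 cholesterol synthesis genes, 13 fell, 2 rose, Mvk among them, and 3 were not called (13 and 2 adjusted over the list alone, median -1.05). The sterol oxidase Msmo1 fell 6.83-fold and squalene epoxidase, Sqle, 4.05-fold. Of 20 lysosome and V-ATPase genes, 15 fell, 3 rose and 2 were not called (15 and 4 adjusted over the list alone, median -0.44). The proton pump subunits Atp6v0b and Atp6v1h fell 4.06-fold and 2.88-fold, and the 3 that rose were Ctsb, Hexa and Lamp2, which are enzymes and a membrane protein of the lysosome. Of 18 nucleolar and ribosome biogenesis genes, 15 fell, 2 rose (Ncl and Npm1) and 1 was not called (15 and 2 adjusted over the list alone, median -0.77). Nop56, part of the complex that methylates ribosomal RNA, fell 3.86-fold and Gnl3 4.24-fold. Camera called the 3 lists (adjusted p = 0.00154, 0.00191 and 0.0006), each with an adjusted p of 0.0692 when the correlation was estimated. Of 26 cytosolic ribosomal protein genes, whose many pseudogenes make them uncertain, 11 were higher, 9 lower and 6 not called (11 and 9 adjusted over the list alone). The list was not called (median 0.07, adjusted p = 0.687).

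Interferon-stimulated genes were mostly higher in the VprBP-labelled libraries. Of 23 tested, 16 rose, 4 fell and 3 were not called (16 and 4 adjusted over the list alone, median 1.10). Usp18, a protease that removes ISG15 from proteins, rose 5.96-fold from 7.45 ± 0.395 to 44.3 ± 2.16 CPM, and Ifit3 11.0-fold. The 4 that fell were the chemokine Cxcl10, 3.69-fold from 553 ± 21.4 to 149.6 ± 2.05 CPM, and the antiviral genes Rsad2, Isg15 and Mx2. The summed level went the other way from the count, at 1562 ± 39.4 CPM in the control-labelled and 1449 ± 22.1 CPM in the VprBP-labelled libraries. Of 9 MHC class II genes, 5 were tested and all 5 rose (5 adjusted over the list alone, median 2.30). Among them Cd74, the invariant chain, rose 3.56-fold from 23.3 ± 0.255 to 82.8 ± 2.45 CPM. H2-Aa, H2-Ab1, H2-Oa and Ciita had too few counts to be tested, and the calls say nothing about them. Ciita stood at 0.159 ± 0.135 and 0.144 ± 0.136 CPM and H2-Ab1 at 0 and 0.444 ± 0.305 CPM. Camera called both lists (adjusted p = 0.00787 and 0.0218), and with an estimated correlation the adjusted p was 0.111 for each. Of 22 inflammatory and NF-kB target genes, 12 were tested, with 8 higher, 3 lower and 1 not called (8 and 3 adjusted over the list alone). The chemokine Cxcl1 stood at 9.31 ± 0.503 and 93.3 ± 5.51 CPM and the adhesion molecule Icam1 was 2.03-fold higher. The 3 lower ones were Ccl4 (2.10 ± 0.345 and 0.0540 ± 0.0935 CPM), Ccl5, 2.22-fold lower, and Relb, 1.66-fold lower. The list was not called (median 0.88, camera adjusted p = 0.13).

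Markers of other cell types differed between the labels as well. Of 8 tested stromal and fibroblast markers, 7 rose in the VprBP-labelled libraries and 1, Dcn, fell (7 and 1 adjusted over the list alone, median 2.31). Their summed level was 2012 ± 42.2 CPM in the control-labelled and 5132 ± 77.5 CPM in the VprBP-labelled libraries, most of it from Sparc (1904 ± 42.7 and 4398 ± 42.3 CPM). Col1a1, a chain of type I collagen, rose 20.3-fold from 14.9 ± 1.07 to 302 ± 28.1 CPM, and Sparc, a matrix glycoprotein that pigment cells also express, 2.31-fold. Camera called the list (adjusted p = 0.00483), with an adjusted p of 0.0892 when the correlation was estimated. The other marker lists had fewer than 5 tested members and were not tested as lists. Summed levels in the control-labelled and VprBP-labelled libraries were 0.239 ± 0.104 and 3.05 ± 0.709 CPM for neutrophil markers, 3.05 ± 0.432 and 3.24 ± 0.690 CPM for B cell markers, and 4.45 ± 0.795 and 2.89 ± 0.304 CPM for T and NK cell markers. Dendritic cell markers summed to 12.1 CPM in the lowest and 15.8 CPM in the highest library. The sums were 3.43 ± 0.230 and 7.57 ± 1.54 CPM for mast cell markers. Erythroid markers summed to 305 ± 7.98 and 421 ± 13.3 CPM, nearly all from the transferrin receptor Tfrc, which dividing cells in general express. Megakaryocyte markers summed to 37.2 ± 3.11 and 12.9 ± 0.965 CPM, endothelial markers to 39.1 ± 2.50 and 119.7 ± 3.19 CPM, mostly from Egfl7, and osteoblast markers to 43.4 ± 3.31 and 68.4 ± 4.99 CPM. Most of the osteoblast sum was the collagen gene Col11a2 (37.0 ± 3.18 and 47.9 ± 5.61 CPM). Of 8 osteoblast markers, 4 have a row. All 4 were tested and rose, Alpl by 7.19-fold and Col11a2 by 1.29-fold.

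Few members of those lists were tested. Of the neutrophil list Prtn3 was higher, and of the B cell list Cd79a was higher and Pax5 was not called. Lck of the T and NK cell list was lower. Zbtb46 of the dendritic cell list was lower over all genes tested and not called when adjusted over the list alone, and Batf3 was not called. Gata2 of the mast cell list was higher and Hdc not called, Tfrc and Epor of the erythroid list were higher and Klf1 lower, Itga2b of the megakaryocyte list was lower and Gp1ba not called, and of the endothelial list Egfl7 was higher and Esam lower. Apart from Zbtb46, the calls in these lists were the same when adjusted over the list alone.

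**Figure D2:**
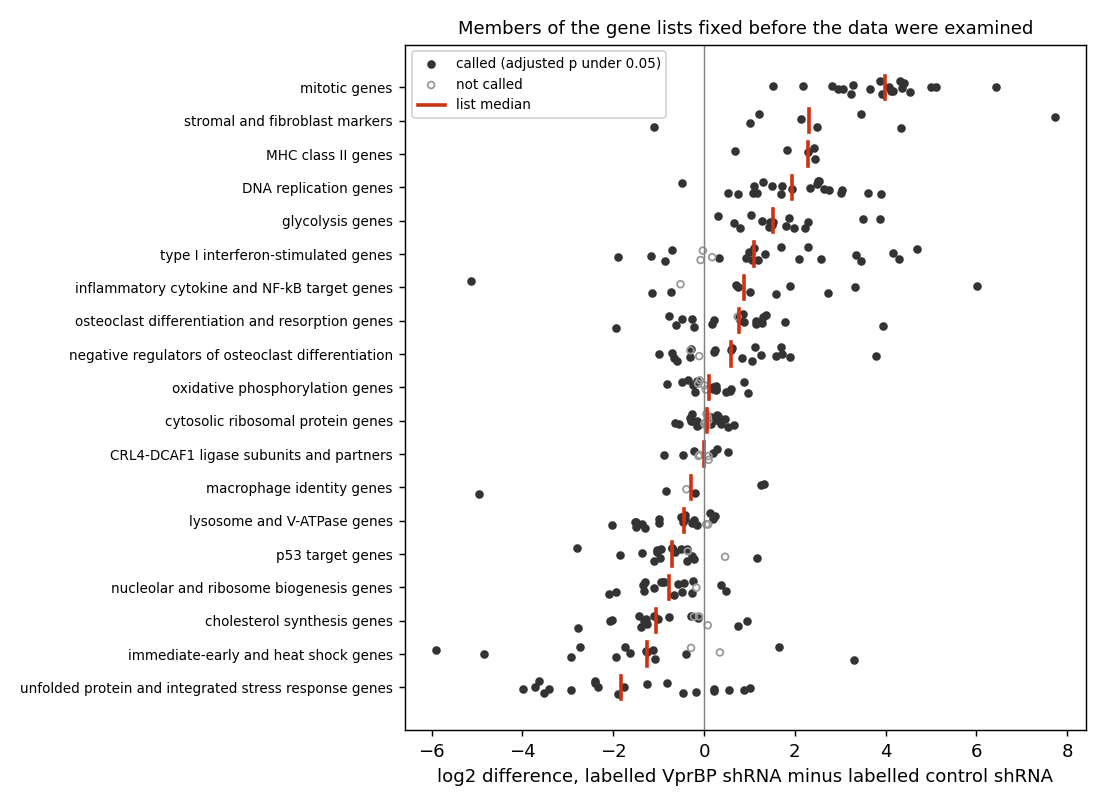
Log2 difference, VprBP-labelled minus control-labelled, of each tested member of the 19 gene lists with at least 5 tested members; filled points were called, open points were not, and red bars are list medians. The mitotic genes lie at a median of 3.99 and the unfolded protein and integrated stress response genes at a median of -1.82.

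In all, camera called 12 of the 19 tested lists with its preset correlation, 6 higher and 6 lower in the VprBP-labelled libraries. With an estimated correlation camera called 0, although 10 lists had an unadjusted p below 0.05, and the self-contained fry test, which compares a list with no other genes, called 18.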

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

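All alternatives but the fit without the 50 most abundant genes were fixed before the data were examined. Directions are between the labels. Over 19 settings and 55 results, 842 values were recomputed, of which 812 kept their direction and side of the threshold or, for a count, stayed within 1.5 times the main one. The 27 genes picked by size or p kept direction and side of the threshold in 401 of 401 refits. Their selection as the most extreme genes of the same libraries makes this likely. The 10974 called genes became 10637 to 10774 when a library was left out, 10945 with DESeq2, 11078 with limma-voom, 11605 without a filter and 9278 with the strict filter. A minimum absolute log2 difference of 1 left 4923 genes, 2843 higher and 2080 lower, by its construction. Library size only made 56.6% of calls higher and ended the call of Dcaf1 (-0.12, adjusted p = 0.137, against 0.00315 to 0.0324 over its other alternatives), because it moved the median of all genes by 0.12 while the SE stayed at 0.07. Camera with an estimated correlation called 0 lists (adjusted p from 0.0571 to 0.111 for the 12 called otherwise), since that test draws on the few residual degrees of freedom of 6 libraries. Fry, which asks another question, called 6 lists that camera did not. These were the osteoclast list (median 0.78, adjusted p = 5.1e-05), the negative regulators (median 0.60, adjusted p = 0.000488), and the CRL4-DCAF1 (adjusted p = 0.0194), macrophage (0.00033), inflammatory (2.03e-06) and oxidative phosphorylation (0.00158) lists. Camera called the inflammatory list with the strict filter alone (adjusted p = 0.0411, against 0.0761 to 0.209 over its other camera fits). The median of the CRL4-DCAF1 list, 0.000328, turned to -0.0238 with upper quartile scaling, -0.0184 with the strict filter and -0.00302 without the 50 genes, and ranged from -0.0100 to 0.0337 with a library left out; the cause was not tested, and camera called the list in none of these fits. With the replicate block 10649 genes were called, 10621 of them among the 10974. Same-numbered libraries did not deviate together (correlations -0.03, 0.01 and -0.04 across genes), and not every library correlated best with its own number. Depth limits genes near 0.144 to 0.186 CPM, the level a count of 0 allows in a library.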

Other observations

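The gene groups of the next 2 paragraphs were chosen after the data were seen, as were the tests of mixed-in pigment cells, of a change of macrophages into pigment cells, all 3 tests on Dcaf1, and the fit without the 50 most abundant genes; the other tests were written before their results were seen. Directions are between labels. Because these groups were picked on the same data, member counts and medians are given for them and no list test. Of 37 proteasome subunit genes, 33 were lower in the VprBP-labelled libraries and 4 higher (median log2 difference -0.68). Psmd8 fell 2.29-fold from 398 ± 3.71 to 174 ± 7.33 CPM. The 4 higher ones were Psmd1 and the immunoproteasome subunits Psmb8, Psmb9 and Psmb10, of which Psmb8 rose 10.7-fold from 1.62 ± 0.746 to 17.4 ± 1.30 CPM. Of 11 MHC class I pathway genes, which include those 3 immunoproteasome subunits, 9 were higher, 1 lower and 1 not called (median 0.45). Of 13 NRF2 target genes, 6 were higher, 6 lower and 1 not called (median 0.03). Hmox1 and the ferritin gene Ftl1 (2.61-fold) fell, while Txnrd1 (2.41-fold) and Me1 (3.28-fold) rose.

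All 10 tested myelin and Schwann lineage genes were higher in the VprBP-labelled libraries (median 3.61). Pmp22 rose 41.9-fold from 2.25 ± 0.453 to 95.1 ± 4.84 CPM and the neuregulin receptor Erbb3, which pigment cells also express, 4.03-fold from 120 ± 10.4 to 483 ± 13.1 CPM. Of 31 tested collagen genes, 26 were higher, 1 lower and 4 not called (median 2.58), with Col4a1 up 10.3-fold. The 18 melanosome lineage genes moved both ways, 8 higher, 7 lower and 3 not called (median -0.11). The lineage transcription factor Sox10 rose from 143 ± 10.3 to 502 ± 33.5 CPM and Tyr, the rate-limiting enzyme of melanin synthesis, from 125 ± 7.43 to 474 ± 26.2 CPM, while the pigment transporter Slc45a2 fell from 807 ± 13.8 to 212 ± 8.11 CPM. Of 9 tested pan-leukocyte genes, 7 were higher and 2 lower (median 3.05). The summed level went the other way, at 27.0 ± 1.60 and 24.3 ± 1.16 CPM. Most of the control-labelled sum was Fermt3 (14.2 ± 1.80 and 3.34 ± 0.136 CPM) and Lcp1 (10.1 ± 1.46 and 4.16 ± 0.718 CPM), which fell. The 7 that rose reached at most 3.97 ± 0.491 CPM (Vav1), so the median rests on low counts.

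Pigment cell transcripts were abundant and macrophage transcripts scarce in all 6 libraries. Pigment cells mixed into a macrophage culture would leave the abundant macrophage transcripts in place. However, the macrophage genes other than Gpnmb and Apoe reached at most 0.192% of the pigment gene sum. Gpnmb and Apoe decide nothing here, because pigment cells also express them. The genes of the pigment sum were chosen on abundance, which makes that share smaller. A change of macrophages into pigment-gene expressing cells by the VprBP shRNA would spare the control-labelled libraries, but their pigment gene sum was 1.07 times that of the VprBP-labelled ones. A set of 10 further pigment cell genes, fixed before their levels were seen, had a median at the 69.8th percentile of listed genes. The 11 pan-leukocyte genes with a row, out of 16, had one at the 32.4th. Both lay on the side foreseen by the hypothesis that the counts come from other cells than the labels name. That pigment level alone does not single out pigment cells. The osteoclast list had a median at the 74.8th percentile over the 24 of its 30 genes with a row. The stromal list, among lists of other kinds, had one at the 62.2nd over 10 of 12. The osteoclast median is no sign of osteoclasts. Clcn7 (399 and 104 CPM) and Mitf, also of pigment cells (27.5 and 94.6 CPM), were well expressed. Acp5 (0.122 and 0.246 CPM) and Ctsk (0.917 and 0.122 CPM) were near the floor in the control-labelled and VprBP-labelled libraries. Whether a table of another experiment or a culture made up of other cells would account for the abundant pigment cell and scarce macrophage transcripts stays open.

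Dcaf1 was only slightly lower in the libraries labelled VprBP shRNA. Exchanged group labels would put Dcaf1 lower in the control-labelled libraries if the shRNA lowered its transcript. The upper bound of the 95% interval of the log2 difference of Dcaf1 was -0.0857. This cannot decide the question, because such a lowering is not shown here, and with scaling by library size only the difference was not called. Too few reads would leave room for a 2-fold depletion, but the lower bound of the 95% interval was -0.386. The counts may come from an experiment without this knockdown: the lowest VprBP-labelled library lay at -0.285 against the control-labelled mean, which cannot be told apart from a weak knockdown because a small difference fits both. A knockdown that acts mainly on the protein also stays open, as untested.

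Stress genes of the endoplasmic reticulum were high and cell cycle genes low in the control-labelled libraries. A few very abundant genes might shift the scaling, but the mitotic median kept 0.999 of its size once the 50 most abundant genes were left out. That refit could hardly have come out otherwise, because a change of scaling moves all genes alike. Library size only moved the median of all genes by 0.116 on the log2 scale, which is small beside the mitotic median of 3.99. A single deviating library would move the medians when left out, but the mitotic and stress lists kept at least 0.978 of theirs. The labels name no culture or library batch (0 batch labels), so none was weighed, and with Dcaf1 barely lowered the difference may not come from VprBP. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes (10974). The highest other gave 0 with edgeR (at most 48 at an unadjusted p below 0.05). Every other split mixes the labels, whose difference then counts as spread within groups, so few or no calls were bound to follow. In addition, 10 splits are too few for a share below 0.05.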
